A study of Drosophila melanogaster with 8 samples.

How the data were processed

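RNA from heads of female flies aged 5 days was sequenced by the authors in 4 genotypes, PA36 (the control in the labels), PR36, (G4C2)36 and UPF1 RNAi. Per the labels, each genotype had 2 replicates from 40 heads in total, RNA was extracted with Trizol, and flies were kept at 24 °C and 60% humidity. Per the submitters' processing notes, the genome build was BDGP6 and bcl2fastq, HISAT2 2.1 and HISAT were used. The program that made the expression values, its annotation release and whether it used strand are not given in the sources used here. The authors deposited 1 table of TPM (a transcript's length-normalized share of reads) for 26309 transcripts. The header holds 10 names and the lines hold 11 cells. Names were read from the left, which gives 7 libraries a column each, and 1 value column without a name was not used. UPF1 RNAi is therefore represented by 1 library, and its second library is not analysed here. Every assignment of values to a library rests on this reading.

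The listed TPM of a library summed to between 712972 and 877933, so the table holds part of what the authors normalized over. In the reference annotation used here (BDGP6, Ensembl release 115), 99.4% of listed transcripts were found, 76.8% of the reference's 30792 protein-coding transcripts were listed, and 0 transcripts of the mitochondrial genome were. Gene values are the sum of a gene's listed transcripts, over 13656 genes, of which 11597 have every reference transcript listed. TPM keep no depth, so the depth is unknown and no counting intervals are given. An exact 0 can be a failed estimate: each library stood below the 6 others by over 2 on the log2 scale in 14 to 32 genes. Genes at 0 are described as listed at 0, with each library's value and no fold.

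The values were analysed as log2(TPM + 1), so fold changes of genes with low TPM are understated. Genes with a mean of at least 1 TPM over the 7 libraries (9287 genes) were tested with limma 3.58.1 in R 4.3.3, with 1 coefficient per genotype and empirical Bayes moderation with a trend, two-sided. The residual degrees of freedom were 3 and the prior degrees of freedom 4.1. Genes with a Benjamini-Hochberg adjusted p below 0.05 within a comparison count as called. The design fixed before the data were examined spoke of 8 libraries and of gene values. With 7 named columns and transcript values the same model was fitted on 7 libraries and summed genes. In all, 6 contrasts were taken, 3 against PA36 and 3 between the other genotypes, and the latter test the difference between effects. Gene lists were fixed before the data were examined, 29 in all with at least 3 genes tested, for NMD, stress, organelles, neurons and the other cell types a head can hold. They were tested with camera at a preset inter-gene correlation of 0.01, with adjustment over the lists of a comparison. Of 174 list tests, 52 were called, and with an estimated correlation 0 were (smallest adjusted p = 0.37). The cuticle list took genes by their name and holds Cpr, which encodes an electron donor of cytochrome P450s, as 1 of its 31 tested members.

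Genes are named by a rule fixed before the data were examined. It took the 8 highest and 8 lowest log2 fold changes against PA36 (5 and 5 between other genotypes) among called genes whose libraries all lie on 1 side of those of the other genotype and whose higher group averages at least 5 TPM, up to 3 called members of each list, the genes called in all 3 comparisons, and every member of the NMD lists and the marker loci. Members of lists given with TPM only, as examples, were chosen after their values were seen. Coordinates are 1-based positions in BDGP6 from the reference annotation.

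The model was tested on simulated data in which 200 of 9287 genes were changed. In PR36 against PA36 it recovered 14.6%, 85.2% and 95.5% of genes changed by 1, 2 and 3 on the log2 scale, with 6.8% false calls. In (G4C2)36 it recovered 16.7%, 86.3% and 96.1% with 8.4% false calls, and in UPF1 RNAi 5.4%, 67.8% and 92.9% with 7.6%. Comparisons with PA36 share its libraries, so overlaps and correlations between them were set beside 100 simulated sets of unchanged groups. Alternatives covered the pseudocount, the filter, median-of-ratios, quantile and coding-gene rescaling, limma's trend and robust options, a fit on the groups compared alone, the replicate number as a block, and each replicate left out in turn. After the data were seen, genes with every transcript listed and a fit without PA36 replicate 1 and PR36 replicate 1 were added. Joins, tests on simulated sets and figures used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9.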

Results

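Gene expression was measured by RNA sequencing in heads of 5-day-old female Drosophila melanogaster that expressed 1 of 4 transgenes through the pan-neuronal driver Elav. PA36 encodes a proline-alanine dipeptide repeat and is the control in the labels. PR36 encodes a proline-arginine repeat, (G4C2)36 carries the GGGGCC repeat that is expanded in C9orf72-linked amyotrophic lateral sclerosis and frontotemporal dementia, and UPF1 RNAi targets the helicase Upf1, which is needed for nonsense-mediated mRNA decay (NMD). The design asks which transcripts the toxic repeats change relative to PA36, and whether they resemble those changed by loss of NMD. Values were used from 2 libraries each of PA36, PR36 and (G4C2)36 and from 1 library of UPF1 RNAi. No label says that the replicates came from separate fly cultures, so the p-values measure the spread between these samples, which may be technical. The authors' values are TPM, summed here per gene. The depth of the libraries is unknown, because TPM keep no read number. The listed transcripts summed to between 712972 and 877933 TPM per library, and 9113 to 9345 genes reached 1 TPM.

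The libraries resembled one another more than they differed by genotype. Pearson correlations of log2(TPM + 1) across 9287 genes, which are not independent replicates, were 0.943 within PA36, 0.948 within PR36 and 0.951 within (G4C2)36, in a range of 0.924 to 0.951 over all pairs. Yolk protein transcripts, made by fat body and ovary, took 16.26% of listed TPM in (G4C2)36 replicate 2 and between 5.05% and 9.79% in the 6 other libraries. Heat shock genes separated PA36 replicate 1 and PR36 replicate 1 from the rest. Hsp70Aa, an inducible chaperone, stood at 1448 and 4.93 TPM in the PA36 libraries and at 2020 and 6.77 TPM in the PR36 libraries. It stood at 153 and 155 TPM in (G4C2)36 and at 14.6 TPM in UPF1 RNAi. Hsp26 stood at 871 and 10.2 TPM in PA36, at 976 and 20.9 TPM in PR36, at 47.4 and 50.4 TPM in (G4C2)36, and at 20.5 TPM in UPF1 RNAi. Hsp70Aa and Hsp70Ab are near-identical copies, so how reads were divided between them is uncertain.

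**Figure D1:**
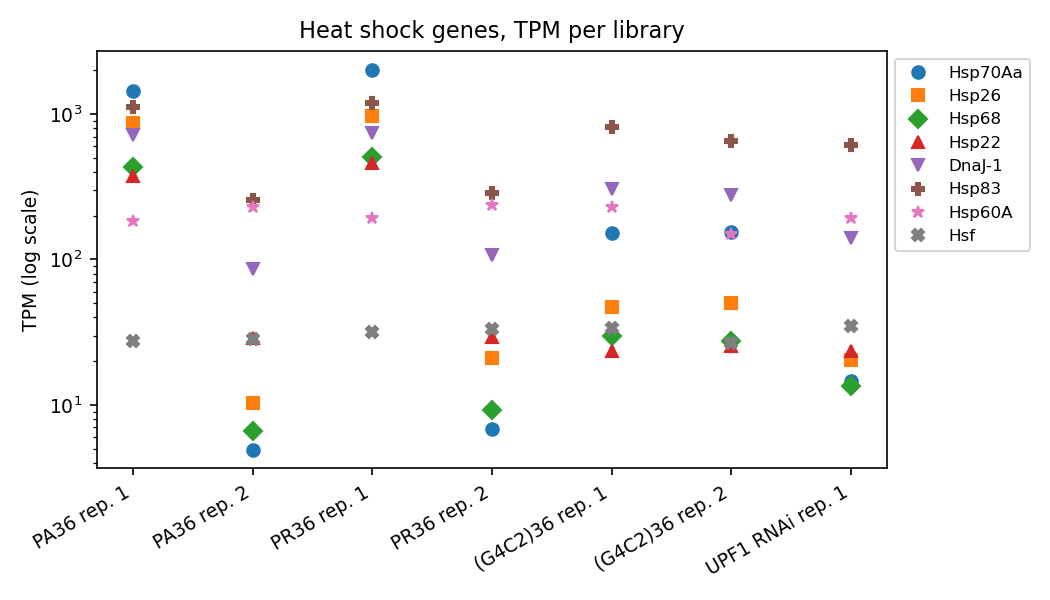
TPM of heat shock genes in each of the 7 libraries, on a log scale, with 1 point per library. PA36 replicate 1 and PR36 replicate 1 lie far above the second library of their genotype, for example at 1448 against 4.93 TPM and at 2020 against 6.77 TPM for Hsp70Aa.

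Upf1 itself (X, 11899996 to 11905371, BDGP6) was listed at 10.3 and 19.1 TPM in PA36, 18.6 and 19.6 TPM in PR36, 18.2 and 16 TPM in (G4C2)36 and 11.3 TPM in UPF1 RNAi. The log2 fold change of UPF1 RNAi against PA36 was -0.29 (SE 0.37, limma adjusted p = 0.96), so the targeted gene did not decide whether the label holds. Gadd45 (2R, 7249161 to 7250655), a stress-response gene, stood at 109 TPM in UPF1 RNAi against 16.7 ± 2.27 TPM (SD, n = 2) in PA36, a log2 fold change of 2.64 (SE 0.33, limma adjusted p = 0.023). It stood at 38 ± 0.827 TPM in PR36 and at 31.6 ± 10.4 TPM in (G4C2)36 (SD, n = 2 each). These log2 fold changes of 1.15 (SE 0.27, adjusted p = 0.47) and 0.85 (SE 0.27, adjusted p = 0.53) did not pass. Arc1 (2R, 14357927 to 14360297), which encodes a capsid-forming protein of synapses, rose from 26.8 ± 4.28 TPM in PA36 to 149 ± 10.3 TPM in PR36 and 98.6 ± 20.9 TPM in (G4C2)36 (SD, n = 2 each). Its log2 fold changes were 2.44 (SE 0.24, adjusted p = 0.017) and 1.83 (SE 0.24, adjusted p = 0.032), while 62.7 TPM in UPF1 RNAi gave 1.20 (SE 0.29, adjusted p = 0.26).

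The list of 4 reported NMD targets (Arc1, Gadd45, Oda and tra) was higher than other genes in all 3 comparisons with PA36. Its median log2 fold change was 0.62 in PR36 (camera adjusted p = 0.0039), 0.51 in (G4C2)36 (adjusted p = 0.021) and 1.01 in UPF1 RNAi (adjusted p = 3.1e-05). With an estimated inter-gene correlation these calls were lost, at adjusted p = 0.84, adjusted p = 0.88 and adjusted p = 0.84. Adjusted over the list alone, 2 members passed in PR36, 2 in (G4C2)36 and 4 in UPF1 RNAi, against 1 in each over all genes tested. In UPF1 RNAi, tra stood at 25.9 TPM against 14.3 and 14.1 TPM in PA36 (adjusted p = 0.66) and Oda at 1850 against 1350 and 1220 TPM (adjusted p = 0.78). The list of 10 NMD and exon junction factors was not called in any comparison with PA36, with medians of 0.18, 0.11 and 0.11 (adjusted p = 0.8, 0.82 and 0.61). Among its members, Smg6, an endonuclease of the pathway, stood at 73.2 TPM in UPF1 RNAi against 37.3 and 43.6 TPM in PA36 (adjusted p = 0.57). The call of Arc1 in (G4C2)36 was lost without PA36 replicate 1 (log2 fold change 1.68, adjusted p = 0.072), (G4C2)36 replicate 1 (1.62, adjusted p = 0.14) or (G4C2)36 replicate 2 (2.05, adjusted p = 0.073). The list's call in (G4C2)36 was lost without PA36 replicate 2 (adjusted p = 0.085). Without both libraries with high heat shock genes, an alternative chosen after seeing the data that leaves 1 library of every genotype but (G4C2)36 and takes the spread from that pair alone, it was lost in PR36 (median 0.58, adjusted p = 0.13) and in (G4C2)36 (0.48, adjusted p = 0.12). Compared directly, the list was lower in (G4C2)36 than in UPF1 RNAi (median -0.56, camera adjusted p = 0.046, or 0.91 with an estimated correlation). This call was lost with median-of-ratios rescaling (adjusted p = 0.056) and with the replicate number as a block (adjusted p = 0.097). In PR36 against UPF1 RNAi it was not called (-0.61, adjusted p = 0.11). Differences between genotypes did not pass for the single genes Gadd45 (UPF1 RNAi against PR36, adjusted p = 0.22; against (G4C2)36, adjusted p = 0.095) or for Arc1 (PR36 against (G4C2)36, adjusted p = 0.87; PR36 against UPF1 RNAi, adjusted p = 0.24).

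**Figure D2:**
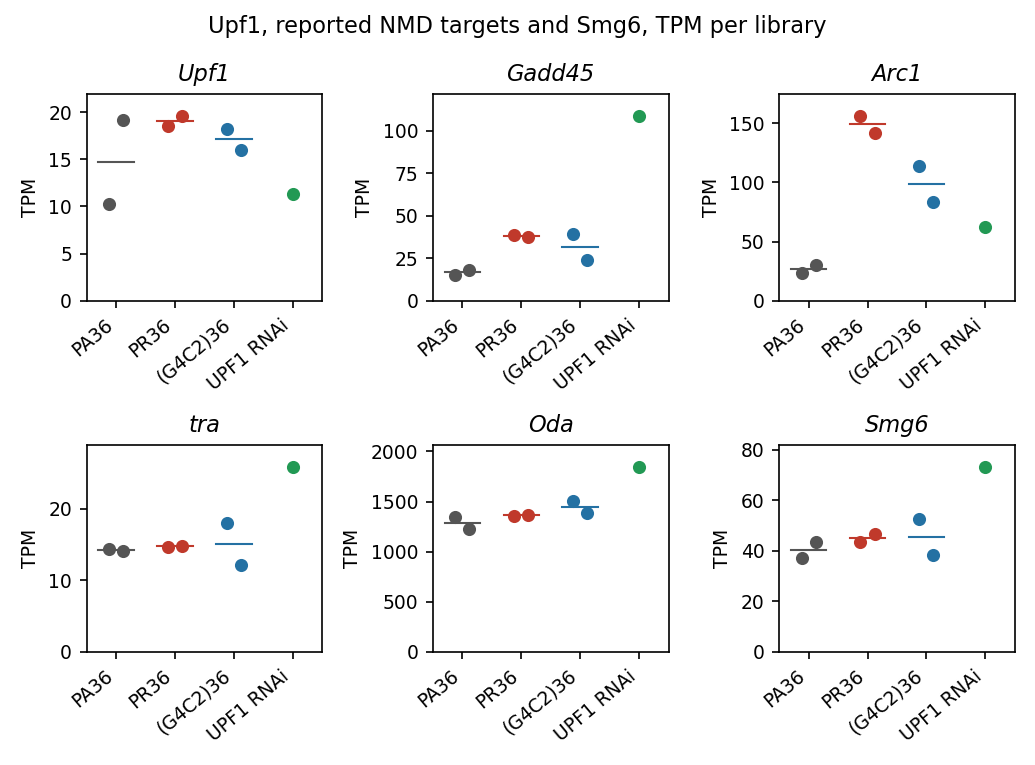
TPM of Upf1, the 4 reported NMD targets and Smg6 per library, with 1 point per library and a bar at the genotype's mean. Gadd45 reaches 109 TPM in UPF1 RNAi against 15.1 and 18.3 TPM in PA36, and Arc1 reaches 156 and 142 TPM in PR36 against 23.8 and 29.8 TPM in PA36.

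PR36 against PA36 asks what the arginine-rich repeat changes relative to the control repeat. Among the 10 genes that rose in PR36 was vermilion (v; X, 10923972 to 10925631), the tryptophan dioxygenase of eye pigment synthesis, at 49.5 ± 2.58 against 3.21 ± 0.62 TPM (SD, n = 2 each; log2 fold change 3.59, SE 0.22, adjusted p = 0.003). The endoplasmic reticulum chaperone calnexin (Cnx99A) rose from 9 ± 1.56 to 101 ± 20.7 TPM (3.35, SE 0.35, adjusted p = 0.018). The ribosomal S6 kinase S6kII rose from 1.03 ± 0.101 to 13.9 ± 3.12 TPM (2.86, SE 0.32, adjusted p = 0.023). Formaldehyde dehydrogenase (Fdh) rose from 10.6 ± 1.96 to 63.8 ± 14.8 TPM (2.47, SE 0.26, adjusted p = 0.018). The cysteine protease Cp1, a cathepsin L (2R, 13960675 to 13967981), fell from 456 ± 33.5 to 7.88 ± 0.629 TPM (-5.69, SE 0.28, adjusted p = 0.0012), although not every reference transcript of Cp1 is listed. Eh, which encodes eclosion hormone, stood at 16.8 and 17.5 TPM in PR36 and at 0.893 and 0 TPM in PA36 (adjusted p = 0.017).

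Several of the other calls rest on genes listed at 0 in every library of a genotype, for which no fold is given. The Hippo pathway kinase gene wts was listed at 0 in both PR36 libraries and at 15.1 and 24.8 TPM in PA36 (adjusted p = 0.0087). CG18731 was listed at 15.8 and 17.9 TPM in PR36 and at 0 in the 5 other libraries (adjusted p = 0.014), and CG32091 at 11.5 and 12.8 TPM against 0 in both PA36 libraries (adjusted p = 0.017). The snoRNA host gene Uhg1 (13 and 10 TPM in PA36) and the hairpin RNA gene hpRNA:CR33940 (7.66 and 7.74 TPM) were listed at 0 in PR36 (adjusted p = 0.018 and 0.042). CG12395 went from 17 and 12.1 TPM to 0 and 0.0797 TPM (adjusted p = 0.017). CG32091, Uhg1, hpRNA:CR33940 and CG12395 were called the same way in (G4C2)36 and UPF1 RNAi too. Sgll, which makes pyridoxal phosphate, fell (log2 fold change -3.28, SE 0.31, adjusted p = 0.017), as did CG42673 (-2.64, SE 0.23, adjusted p = 0.014) and Su(fu), an inhibitor of Hedgehog signalling (-2.89, SE 0.34, adjusted p = 0.033). Sgll was also low in (G4C2)36 (6.68 and 9.89 TPM) and UPF1 RNAi (8.4 TPM), against 39.7 and 46.5 TPM in PA36. CG7084 rose by 3.10 (SE 0.34, adjusted p = 0.021) and mir-281-2, a microRNA precursor inside the Oda locus, by 3.40 (SE 0.34, adjusted p = 0.017). With a pseudocount of 0.1, the calls of CG18731 (limma adjusted p = 0.3), Eh (0.32) and mir-281-2 (0.26) were lost. So were those of Uhg1 (0.44), CG12395 (0.34) and hpRNA:CR33940 (0.72). Without PA36 replicate 1 the calls of Su(fu) (adjusted p = 0.055) and hpRNA:CR33940 (adjusted p = 0.084) were lost, and the latter also without PA36 replicate 2 (adjusted p = 0.071).

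In all, 10 genes were higher and 8 lower in PR36 than in PA36 of 9287 tested, by limma with Benjamini-Hochberg adjustment, and 315 genes had an unadjusted p below 0.05. With no change at all, a share of 0.05 of the tested genes would be expected there, which is more than 315. That count is therefore no sign of further changes. The median log2 fold change over all genes was 0.126 here, 0.134 in (G4C2)36 and 0.104 in UPF1 RNAi, and rescaling by the median of ratios brought these to 0.007, 0.014 and 0.015. For some lists, such as ribosomal proteins and oxidative phosphorylation in (G4C2)36, changes are therefore also given relative to that median. Which direction prevailed depended on the libraries. Without PA36 replicate 1, 40 genes were higher and 12 lower, and without PA36 replicate 2, 41 and 16. Without PR36 replicate 1, 16 were higher and 24 lower, and without PR36 replicate 2, 15 and 42. Without both libraries with high heat shock genes, which sets 1 library against 1 with the spread of the (G4C2)36 pair, the count was 198 genes, so it does not show which calls hold.

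Cytosolic ribosomal proteins were called lower than other genes in PR36, with 53 of 85 members below 0, a median of -0.02 and a relative median of -0.15 (camera adjusted p = 0.00035; adjusted p = 0.96 with an estimated correlation), but no member passed. RpL7 stood at 2524 and 2828 TPM in PR36 against 2667 and 2691 TPM in PA36. The call of this list was lost without PA36 replicate 1 (adjusted p = 0.19), and its median turned to 0.06 without PR36 replicate 1. Without PR36 replicate 1 the median over all genes was 0.205, so the ribosomal protein median still lay below it. Glutathione transferases and antioxidants had a median of 0 and a mean of -0.01 over 34 genes (camera adjusted p = 0.036; adjusted p = 0.96 with an estimated correlation). The 40 odorant-binding and chemosensory genes had a median of -0.03 and a mean of 0.01 with a test direction of lower (adjusted p = 0.047; adjusted p = 0.96 with an estimated correlation). Head fat body and yolk genes had a median of 0.05 but a mean of -0.13 and were called lower (adjusted p = 0.042; adjusted p = 0.84 with an estimated correlation). The lipophorin gene apolpp stood at 339 and 149 TPM in PR36 against 949 and 943 TPM in PA36 (adjusted p = 0.21). The 3 gut digestive enzymes tested were lower (median -0.64, adjusted p = 0.036; adjusted p = 0.84 with an estimated correlation). The transgene and marker loci were higher (median 0.42, adjusted p = 0.042; adjusted p = 0.84 with an estimated correlation), where v was the member that passed. Leaving out PA36 replicate 1 ended the antioxidant, chemosensory, fat body and gut calls (adjusted p = 0.61, 0.61, 0.61 and 0.15). Without PR36 replicate 1 the antioxidant, chemosensory, gut and marker calls were lost (adjusted p = 0.093, 0.67, 0.49 and 0.62). PR36 replicate 2 ended the antioxidant and fat body calls (adjusted p = 0.16 each), and PA36 replicate 2 the marker call (adjusted p = 0.14). Median-of-ratios rescaling ended the gut, chemosensory, fat body and marker calls (adjusted p = 0.17, 0.17, 0.065 and 0.066), and a pseudocount of 0.1 the chemosensory call (adjusted p = 0.055). The unfolded protein and integrated stress response list was not called (20 of 22 members above 0, median 0.10, relative median -0.02, camera adjusted p = 0.15). Nor was the synaptic list (25 of 31 above 0, median 0.24, relative median 0.11, camera adjusted p = 0.18).

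(G4C2)36 against PA36 asks what the repeat RNA and its translation products change. The genes listed at 0 in all 5 libraries of the other genotypes included Idh3b, a subunit of mitochondrial isocitrate dehydrogenase, at 295 and 212 TPM in (G4C2)36 (adjusted p = 0.00019). Others were the kinetochore gene Ndc80 at 41.1 and 37.2 TPM (adjusted p = 0.0012) and CG3397 at 35 and 33.6 TPM (adjusted p = 0.0012). The ERK kinase gene rolled (rl) rose from 0.402 ± 0.167 to 39.7 ± 26.3 TPM (SD, n = 2 each; log2 fold change 4.70, SE 0.45, adjusted p = 0.0086). The enhancer of rudimentary e(r) rose from 2.11 ± 0.634 to 65.8 ± 30.8 TPM (4.36, SE 0.36, adjusted p = 0.0042). Amy-d, an amylase, rose from 4.35 ± 0.159 to 36 ± 13.4 TPM (2.74, SE 0.37, adjusted p = 0.039). The genes v (3.33, SE 0.22, adjusted p = 0.0013), Fdh (3.21, SE 0.26, adjusted p = 0.0042), Cnx99A (2.94, SE 0.35, adjusted p = 0.022) and S6kII (2.69, SE 0.32, adjusted p = 0.022) were higher here as in PR36. Cp1 was lower (-5.96, SE 0.28, adjusted p = 0.00028).

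Red, named for the colour of the Malpighian tubules of its mutants, fell from 59.5 ± 3.86 to 4.40 ± 0.306 TPM (-3.48, SE 0.21, adjusted p = 0.0012). CG10638 fell from 25 ± 2.95 to 1.38 ± 0.409 TPM (-3.45, SE 0.26, adjusted p = 0.003), and phu from 76.5 ± 7.6 to 3.01 ± 1.55 TPM (-4.32, SE 0.42, adjusted p = 0.0086). CG34325 (46 and 36.2 TPM in PA36, adjusted p = 0.00028) and the heparan sulfate sulfotransferase gene Hs3st-A (20.5 and 32.9 TPM, adjusted p = 0.0012) were listed at 0 in both (G4C2)36 libraries. So were CG12395, Uhg1 and hpRNA:CR33940 (adjusted p = 0.0086, 0.013 and 0.029). CG32091 stood at 18.1 and 9.5 TPM against 0 in PA36 (adjusted p = 0.006). CG45086 stood at 10.8 and 14.2 against 0.0392 and 0.045 TPM (adjusted p = 0.011), and lectin-46Cb at 15.5 and 13.1 against 0.207 and 0.187 TPM (adjusted p = 0.035). With a pseudocount of 0.1, the calls of Ndc80 (limma adjusted p = 0.058), CG3397 (0.075), CG45086 (0.16), lectin-46Cb (0.19) and Amy-d (0.095) were lost. So were those of CG12395 (0.2), Uhg1 (0.3), hpRNA:CR33940 (0.4) and the cuticle gene Cpr92F (0.091). Of 25 named calls, 13 were lost without (G4C2)36 replicate 1 and 11 without replicate 2. Among them were Amy-d (adjusted p = 0.11 and 0.22), S6kII (0.11 and 0.053), phu (0.063 and 0.094), Uhg1 (0.074 and 0.071), CG12395 (0.062 and 0.062), CG45086 (0.074 and 0.099), lectin-46Cb (0.24 and 0.22) and hpRNA:CR33940 (0.099 and 0.099), all as limma adjusted p. Fdh (adjusted p = 0.06) and Cnx99A (adjusted p = 0.082) were lost without replicate 1 alone. Amy-d and hpRNA:CR33940 also lost their calls without either PA36 library (adjusted p = 0.055 and 0.056 without replicate 1, 0.054 and 0.058 without replicate 2).

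Without either (G4C2)36 library, the log2 fold changes of Uhg1, CG12395 and hpRNA:CR33940 stayed as in the full fit, since both libraries list them at 0. Their calls were therefore not lost through their fold changes. A smaller group, the estimate of the spread and the adjustment over genes all change in such a fit and were not told apart. How many calls a left-out library ends therefore does not rank how far calls rest on it. Over all genes, 24 were higher and 12 lower in (G4C2)36 than in PA36 by limma, and 627 had an unadjusted p below 0.05. Without PA36 replicate 1, 70 were higher and 16 lower, and without PA36 replicate 2, 56 and 20. Without (G4C2)36 replicate 1, 9 were higher and 13 lower, and without (G4C2)36 replicate 2, 16 and 16. The count was 288 without both libraries with high heat shock genes, against 1 PA36 library and with the spread of the (G4C2)36 pair alone.

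Cytosolic ribosomal protein transcripts were lower in (G4C2)36: 83 of 85 members lay below 0, with a median of -0.43 and a relative median of -0.56 (camera adjusted p = 1.7e-43; adjusted p = 0.71 with an estimated correlation), while no member passed alone. The median was -0.62 without (G4C2)36 replicate 1 and -0.25 without (G4C2)36 replicate 2. The median over all genes was -0.027 and 0.312 in these fits, so the list's median lay below it in both. RpL7 stood at 2232 and 1738 TPM against 2667 and 2691 TPM in PA36, and RpS3 at 1676 and 1197 against 1987 and 2077 TPM. The nucleolus and ribosome biogenesis list was lower as well (18 of 24 members below 0, median -0.22, camera adjusted p = 2.9e-05; adjusted p = 0.89 with an estimated correlation). Its median was 0.07 without (G4C2)36 replicate 2, still below the 0.312 of all genes in that fit. Oxidative phosphorylation genes were higher, with 63 of 65 members above 0 and a median of 0.32, or 0.18 relative to all genes (adjusted p = 2.9e-05; adjusted p = 0.92 with an estimated correlation). That call was lost without PA36 replicate 2 (median 0.24, adjusted p = 0.42), and the median was 0.10 without (G4C2)36 replicate 1 and 0.53 without (G4C2)36 replicate 2. Without either (G4C2)36 library, this list's median lay above that over all genes (-0.027 without replicate 1 and 0.312 without replicate 2). ATPsynbeta, a subunit of ATP synthase, stood at 2679 and 2004 TPM against 1768 and 1538 TPM in PA36. Muscle markers were higher, with 17 of 18 members above 0, a median of 0.71 (adjusted p = 3.8e-09; adjusted p = 0.71 with an estimated correlation). Of these, 9 passed adjusted over the list alone, but none over all genes. The actin gene Act57B stood at 2409 and 2343 TPM against 1302 and 1195 TPM in PA36, and myosin heavy chain (Mhc) at 342 and 276 against 130 and 85.8 TPM.

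Cuticle protein genes were higher in (G4C2)36 (23 of 31 above 0, median 0.56, adjusted p = 0.0021; adjusted p = 0.89 with an estimated correlation). Cpr92F rose from 0.333 ± 0.176 to 9.21 ± 2.98 TPM (SD, n = 2 each; log2 fold change 2.91, adjusted p = 0.039). Cpr76Bd stood at 6.89 and 7.97 TPM against 0 in PA36 (adjusted p = 0.022). All 10 circadian clock genes tested lay below 0 (median -0.22, adjusted p = 0.0021; adjusted p = 0.71 with an estimated correlation). That median was -0.48 without (G4C2)36 replicate 1 and -0.03 without (G4C2)36 replicate 2. The median over all genes was -0.027 and 0.312 in these fits, so the list's median lay below it in both. Among the clock genes, tim stood at 16.4 and 4.05 TPM against 9.72 and 23.4 TPM in PA36. The gene per stood at 8.14 and 6.34 against 9.83 and 7.29 TPM, and no member passed. The 3 gut digestive enzymes had a median of 1.47, with 2 above and 1 below 0 (camera adjusted p = 0.04; adjusted p = 0.71 with an estimated correlation). This call did not survive leaving out PA36 replicate 2 (adjusted p = 0.085), leaving out (G4C2)36 replicate 2 (0.71, adjusted p = 0.3), median-of-ratios rescaling (adjusted p = 0.12) or a pseudocount of 0.1 (adjusted p = 0.065). The cuticle call was lost without the same libraries (adjusted p = 0.16 and 0.19). Both single cuticle genes lost theirs without either (G4C2)36 library (Cpr92F at adjusted p = 0.21 and 0.11, Cpr76Bd at 0.11 and 0.14) and Cpr92F also without PA36 replicate 2 (adjusted p = 0.058). The heat shock list was not called (median -0.22, adjusted p = 0.11), and its sign rests on PA36 replicate 1. The list's median deviation from the mean of all libraries was 2.08 and -1.26 in PA36 and 0.02 and -0.15 in (G4C2)36. Against PA36 replicate 2 alone, the log2 fold change of Hsp70Aa in (G4C2)36 was 4.71, with no spread of PA36 left to test it. Also not called were fat body and yolk genes (median 0.33, adjusted p = 0.06). The larval serum protein gene Lsp2 stood at 224 and 1425 TPM against 26.4 and 25.9 TPM in PA36 (adjusted p = 0.16).

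**Figure D3:**
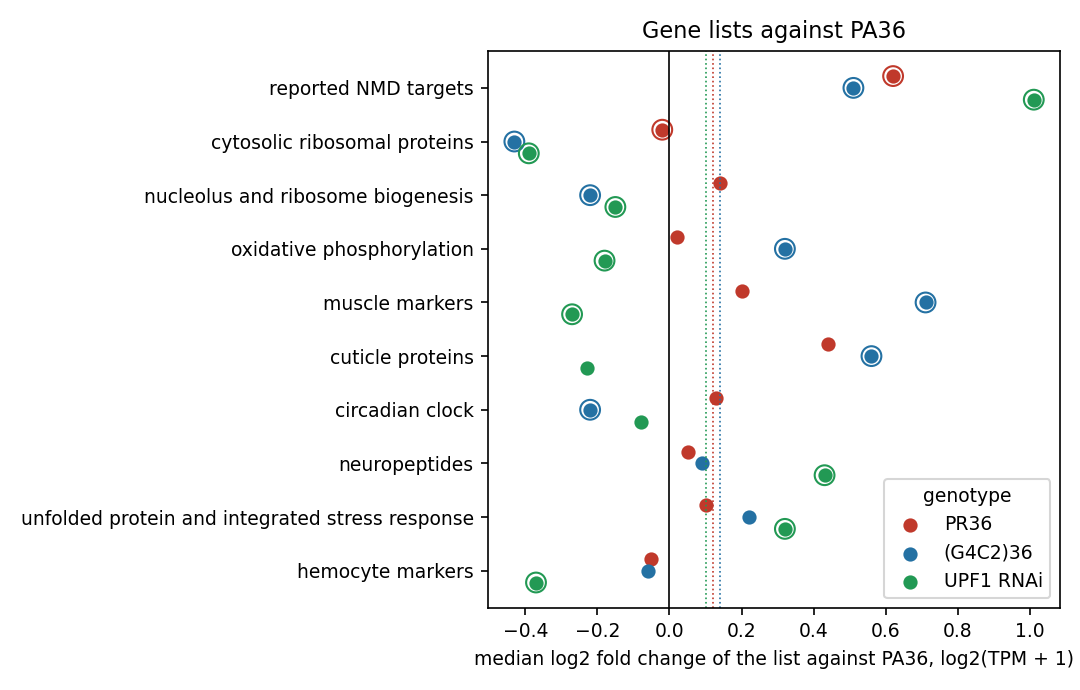
Median log2 fold change of 10 of the 29 gene lists against PA36 in PR36, (G4C2)36 and UPF1 RNAi, with 1 dot per list and genotype. Rings mark camera adjusted p below 0.05 and dotted lines the median of all genes (0.126, 0.134 and 0.104). Ribosomal proteins lie at -0.02, -0.43 and -0.39, and muscle markers at 0.20, 0.71 and -0.27.

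UPF1 RNAi against PA36 asks what loss of the NMD helicase changes. A single library stood for this genotype and was assumed to vary like the others, so the values below are those of that library. Besides Gadd45, it was higher in the cytochrome P450 gene Cyp4e3 (118 against 18.4 ± 6.54 TPM, SD, n = 2; log2 fold change 2.66, SE 0.36, adjusted p = 0.032). Calnexin Cnx99A (129 TPM; 3.71, SE 0.43, adjusted p = 0.016), Fdh (122 TPM; 3.42, SE 0.32, adjusted p = 0.0064) and v (40.4 TPM; 3.31, SE 0.27, adjusted p = 0.0045) were higher too. The same held for e(r) (49.7 TPM; 4.04, SE 0.44, adjusted p = 0.014), rl (22 TPM; 4.04, SE 0.56, adjusted p = 0.035) and S6kII (12.4 TPM; 2.73, SE 0.39, adjusted p = 0.039). Phk-3 stood at 32.2 against 0.8 and 0.964 TPM (4.14, SE 0.34, adjusted p = 0.0045). The pre-rRNA gene pre-rRNA:CR45847 stood at 53.6 against 0.251 and 0.241 TPM (5.45, SE 0.47, adjusted p = 0.0045), and Eh at 27.7 against 0.893 and 0 TPM (adjusted p = 0.013). CG11313 stood at 17.7 TPM and CG32091 at 7.68 TPM, both against 0 in PA36 (adjusted p = 0.023 and 0.032). With a pseudocount of 0.1, the calls of CG11313, pre-rRNA:CR45847 and Eh were lost.

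On the lower side, CG5059 stood at 2.07 TPM in UPF1 RNAi against 234 ± 31.5 TPM in PA36 (log2 fold change -6.25, SE 0.27, adjusted p = 0.00056). Ip259 stood at 16 against 326 ± 18.8 TPM (-4.26, SE 0.24, adjusted p = 0.0017) and Cp1 at 11.4 against 456 ± 33.5 TPM (-5.20, SE 0.34, adjusted p = 0.002). The complex I subunit gene ND-39 stood at 35.7 against 337 ± 2.29 TPM (-3.20, SE 0.43, adjusted p = 0.032). The ribosomal protein gene RpL34a stood at 32.7 against 173 ± 7.9 TPM (-2.37, SE 0.26, adjusted p = 0.014) and the cytochrome P450 gene Cyp4d20 at 7.25 against 28.5 ± 1.5 TPM (-1.84, SE 0.26, adjusted p = 0.039). Genes listed at 0 in this library included CG32581 (43.1 and 80.3 TPM in PA36, adjusted p = 0.0025), the kinesin-associated gene Kap3 (28 and 37.8 TPM, adjusted p = 0.002), Hs3st-A (adjusted p = 0.004) and wts (adjusted p = 0.0064). Further ones were CG14969 (15.8 and 17.2 TPM, adjusted p = 0.002), Cyp12a5 (10.4 and 10.9 TPM, adjusted p = 0.004), CG12395, Uhg1 and hpRNA:CR33940 (adjusted p = 0.019, 0.027 and 0.047). The calls of Cyp4d20 (adjusted p = 0.12 and 0.074), S6kII (0.059 and 0.055) and hpRNA:CR33940 (0.12 and 0.093) were lost without PA36 replicate 1 or 2, and that of Uhg1 without replicate 1 (0.074).

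In total 20 genes were higher and 38 lower than in PA36 by limma, with 594 at an unadjusted p below 0.05. The balance turned to 58 higher and 21 lower without the filter on low values, and to 50 and 43 without PA36 replicate 2, while 36 were higher and 37 lower without PA36 replicate 1. This library stood apart from the 6 others by over 2 on the log2 scale in 36 genes, and each of those 6 stood apart in 18 to 37 genes. The count was 243 without both libraries with high heat shock genes, where 1 library stands against 1 with the spread of the (G4C2)36 pair, and 0 (677 at an unadjusted p below 0.05) when limma was fitted on PA36 and UPF1 RNAi alone.

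Ribosomal protein transcripts were lower in UPF1 RNAi too, with 83 of 85 members below 0 and a median of -0.39, or -0.49 relative to all genes (camera adjusted p = 2.2e-21; adjusted p = 0.84 with an estimated correlation). RpL34a was the member that passed. The nucleolus and ribosome biogenesis list was lower (17 of 24 below 0, median -0.15, adjusted p = 0.016; adjusted p = 0.85 with an estimated correlation). Oxidative phosphorylation genes were lower, with 57 of 65 members below 0 and a median of -0.18 (adjusted p = 3.1e-05; adjusted p = 0.85 with an estimated correlation); of these ND-39 passed. Neuropeptide genes were higher, with 22 of 24 above 0 and a median of 0.43 (adjusted p = 0.0014; adjusted p = 0.84 with an estimated correlation). The precursor sNPF stood at 216 TPM against 91.9 and 114 TPM in PA36, and Ms (myosuppressin) at 355 against 214 and 233 TPM. Synaptic and neuronal genes were higher (25 of 31 above 0, median 0.42, adjusted p = 0.034; adjusted p = 0.85 with an estimated correlation). So was the unfolded protein and integrated stress response list (20 of 22 above 0, median 0.32, adjusted p = 0.002; adjusted p = 0.85 with an estimated correlation). There Cnx99A passed and Hsc70-3, the endoplasmic reticulum Hsp70, stood at 257 against 191 and 178 TPM. The synaptic call was lost without PA36 replicate 1 (median 0.25, adjusted p = 0.75), as was the oxidative phosphorylation call (-0.10, adjusted p = 0.17), and the nucleolus call was lost without PA36 replicate 2 (-0.01, adjusted p = 0.15). Without both libraries with high heat shock genes, the neuropeptide and unfolded protein calls were lost too (medians 0.41 and 0.23, adjusted p = 0.058 each).

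The hemocyte, fat body and muscle lists were called lower in UPF1 RNAi, while glial markers were not called (median 0.12, adjusted p = 0.81). Hemocyte markers had a median of -0.37, with 8 of 9 below 0 (adjusted p = 0.002; adjusted p = 0.84 with an estimated correlation), which was -0.58 without PA36 replicate 1 and -0.22 without PA36 replicate 2. The prophenoloxidase genes PPO1 and PPO2 stood at 18.2 against 35.5 and 64 TPM and at 26.7 against 49.9 and 77.7 TPM. Fat body and yolk genes had a median of -0.23, with 11 of 14 below 0 (adjusted p = 0.0083; adjusted p = 0.84 with an estimated correlation). Muscle markers had one of -0.27, with 13 of 18 below 0 (adjusted p = 0.036; adjusted p = 0.85 with an estimated correlation). The heat shock list had a median of -1.23, with 15 of 19 below 0 (adjusted p = 0.034; adjusted p = 0.85 with an estimated correlation), against PA36 libraries of which 1 had high heat shock genes. Without PA36 replicate 1 that median turned to 0.33 (adjusted p = 0.43), and the muscle and fat body calls were lost as well (medians -0.03 and -0.23, adjusted p = 0.77 and 0.19). Rescaling by the median of ratios also ended the heat shock call (adjusted p = 0.29) and the muscle call (adjusted p = 0.09).

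Of the genes called in any comparison with PA36, 9 were called in the same direction in all 3. The genes v, Fdh, Cnx99A, S6kII and CG32091 were higher, and Cp1, CG12395, Uhg1 and hpRNA:CR33940 lower, in PR36, (G4C2)36 and UPF1 RNAi. With a pseudocount of 0.1, CG12395, Uhg1 and hpRNA:CR33940 lost their calls in all 3 comparisons. Their limma adjusted p were then 0.34, 0.44 and 0.72 in PR36 and 0.2, 0.3 and 0.4 in (G4C2)36. In 100 simulated sets of unchanged groups, with PA36 libraries drawn anew and shared by the comparisons, no gene was called in all 3. For pairs of comparisons, 6 genes were higher and 5 lower in both PR36 and (G4C2)36, 6 higher and 6 lower in both PR36 and UPF1 RNAi, and 9 higher and 7 lower in both (G4C2)36 and UPF1 RNAi. Simulation gave at most 1 such gene, and independent lists of these sizes would share at most 0.052. Unchanged groups yield few calls that could overlap, and independent lists share no control. Neither value therefore shows how much the shared PA36 libraries add to lists of these sizes. With a PA36 library of its own for each comparison, in both ways to assign them, 5 and 6 genes were higher and 4 and 3 lower in both PR36 and (G4C2)36. The same numbers were 4 and 6 higher and 4 and 5 lower for PR36 and UPF1 RNAi, and 7 and 9 higher and 5 and 6 lower for (G4C2)36 and UPF1 RNAi. The PA36 libraries could not be split into sets of 2, so part of these overlaps may come from the shared controls.

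**Figure D4:**
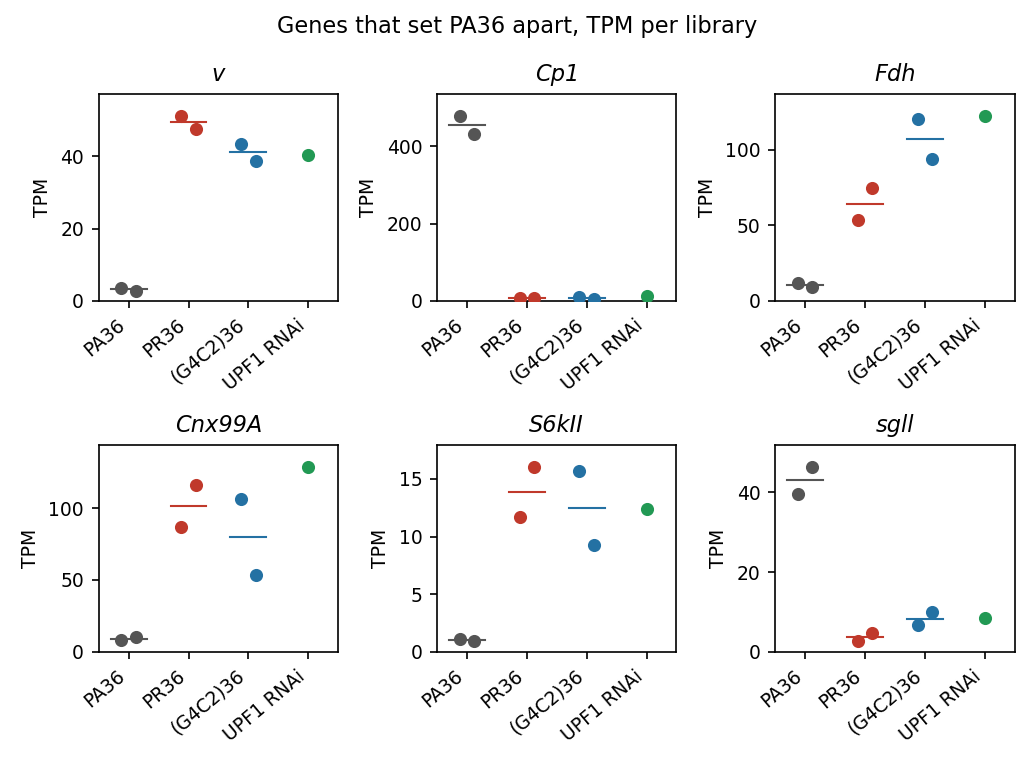
TPM of 5 of the 9 genes called in all 3 comparisons with PA36 and of sgll, with 1 point per library and a bar at the genotype's mean. Both PA36 libraries lie on 1 side of the 5 others in each panel, as for v at 3.64 and 2.77 TPM against 38.7 to 51.3 TPM.

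Across all tested genes, the fold changes of PR36 and (G4C2)36 correlated at 0.49, of PR36 and UPF1 RNAi at 0.37, and of (G4C2)36 and UPF1 RNAi at 0.36 (Pearson, across genes, which are not independent replicates). Simulated unchanged groups gave 0.50, 0.41 and 0.41. The covariances were 0.129, 0.117 and 0.132, which differed from the simulated ones of 0.115, 0.116 and 0.115 by 0.014, 0.001 and 0.017, with standard deviations over simulations of 0.011, 0.012 and 0.014. With 1 PA36 library for each comparison the correlations fell to between -0.06 and 0.12. None of the correlations exceeded its simulated value.

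Compared directly, PR36 and (G4C2)36 differed in 22 genes, 10 higher and 12 lower in PR36, with 488 at an unadjusted p below 0.05. That number is little above a share of 0.05 of all tested genes, which would be expected with no change. Idh3b, Ndc80 and CG3397 were listed at 0 in PR36 (adjusted p = 0.00019, 0.0013 and 0.0015). The gene wts was listed at 0 in PR36 and at 29.1 and 21.8 TPM in (G4C2)36 (adjusted p = 0.002), and e(r) was lower in PR36 (-3.72, SE 0.36, adjusted p = 0.0099). CG34325 (43.2 and 53 TPM in PR36), Hs3st-A (31.1 and 32.2 TPM), Eh (16.8 and 17.5 TPM) and CG18731 (15.8 and 17.9 TPM) were listed at 0 in (G4C2)36 (adjusted p = 0.00023, 0.0012, 0.0067 and 0.0056), and mir-281-2 was higher in PR36 (4.78, SE 0.34, adjusted p = 0.0021). Ribosomal proteins were higher in PR36 than in (G4C2)36 (81 of 85 members, median 0.40, camera adjusted p = 3.2e-27; adjusted p = 0.95 with an estimated correlation). Nucleolus genes were too (23 of 24, median 0.34, adjusted p = 2.3e-06; adjusted p = 0.98 with an estimated correlation). Oxidative phosphorylation genes (63 of 65 lower, median -0.32, adjusted p = 8.2e-11; adjusted p = 0.98 with an estimated correlation) and muscle markers (16 of 18 lower, median -0.48, adjusted p = 2.1e-08; adjusted p = 0.58 with an estimated correlation) were lower in PR36. Fat body and yolk genes were lower as well (12 of 14, median -0.47, adjusted p = 3.1e-06; adjusted p = 0.37 with an estimated correlation). In this comparison 16 genes were higher and 35 lower without PR36 replicate 1, 13 and 55 without PR36 replicate 2, 16 and 8 without (G4C2)36 replicate 1, and 16 and 14 without (G4C2)36 replicate 2.

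PR36 and UPF1 RNAi differed in 40 genes, 32 higher and 8 lower in PR36 (569 at an unadjusted p below 0.05). The balance turned to 17 higher and 48 lower without the filter on low values and to 30 and 44 without PR36 replicate 2, and was 30 and 24 without PR36 replicate 1. The largest included CG5059 (log2 difference 6.37, SE 0.27, adjusted p = 0.00049), mir-281-2 (4.94, SE 0.42, adjusted p = 0.0046) and, all listed at 0 in UPF1 RNAi, CG32581 (71.2 and 93.9 TPM in PR36), Kap3 (36 and 41.6 TPM) and Hs3st-A (adjusted p = 0.0018, 0.0015 and 0.0032). Lower in PR36 were pre-rRNA:CR45847 (-5.66, SE 0.47, adjusted p = 0.0043), Phk-3 (-4.08, SE 0.34, adjusted p = 0.0045), CG11313 (0.309 and 0 against 17.7 TPM, adjusted p = 0.033), e(r) (-3.41, SE 0.44, adjusted p = 0.033) and Cyp4e3 (-2.86, SE 0.36, adjusted p = 0.032). Ribosomal proteins were higher in PR36 (82 of 85 members, median 0.37, camera adjusted p = 2.5e-12; adjusted p = 0.91 with an estimated correlation). Neuropeptides were lower (20 of 24, median -0.44, adjusted p = 8.7e-06; adjusted p = 0.90 with an estimated correlation). (G4C2)36 and UPF1 RNAi differed in 54 genes, 44 higher and 10 lower in (G4C2)36 (696 at an unadjusted p below 0.05), and the balance turned to 35 and 53 without the filter. Lsp2 was higher in (G4C2)36, at 224 and 1425 against 0.931 TPM (8.20, SE 1.05, adjusted p = 0.024). So was CG5059 (6.10, SE 0.27, adjusted p = 4e-04), while CG10638 (-4.01, SE 0.32, adjusted p = 0.0026) and pre-rRNA:CR45847 (-5.57, SE 0.47, adjusted p = 0.0033) were lower. Eh, CG34325 and CG11313 were listed at 0 in (G4C2)36 and at 27.7, 32.3 and 17.7 TPM in UPF1 RNAi (adjusted p = 0.0067, 0.0012 and 0.023), and Idh3b, Ndc80 and CG32581 (78.8 and 59.2 TPM in (G4C2)36) at 0 in UPF1 RNAi (adjusted p = 4e-04, 0.0026 and 0.0018). Fat body and yolk genes (13 of 14 higher, median 0.62, adjusted p = 1.2e-05; adjusted p = 0.42 with an estimated correlation) and cuticle genes (21 of 31, median 0.60, adjusted p = 1.2e-05; adjusted p = 0.91 with an estimated correlation) were higher in (G4C2)36. Neuropeptides were lower (19 of 24, median -0.35, adjusted p = 0.00069; adjusted p = 0.80 with an estimated correlation).

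Exons of Cp1, Uhg1, S6kII, Ip259, Kap3, Phk-3, CG34325, CG45086, CG10638, CG14969, sgll, Oda, tra, Lsp2, mir-281-2, hpRNA:CR33940 and pre-rRNA:CR45847 overlap another annotated gene, and no source used here says whether counting used strand, so their values are uncertain. Of 9 called genes at or near 0 in a genotype with a listed overlapping partner, 3 had a partner that moved the opposite way by at least 1 (log2). In UPF1 RNAi these were Phk-3 with CG3776 (-3.69), Uhg1 with CG46315 (3.03) and pre-rRNA:CR45847 with 28SrRNA:CR45844 (-1.84). For them, reads assigned differently within the pair cannot be told apart from a change. Of the calls, 17 of 18 in PR36, 31 of 36 in (G4C2)36 and 47 of 58 in UPF1 RNAi concern genes with every reference transcript listed. Among the named genes, Cp1, rl, e(r), red, RpL34a, ND-39 and Kap3 lack at least 1.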

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

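In this part, the tests of complete listing, of how many genes set pairs of libraries apart, of the (G4C2)36 replicates for heat shock genes, and of the genes that differ from PA36 in all 3 comparisons were chosen only after the result was seen, and the others were set beforehand. The gene lists that moved in opposite directions in different genotypes are given first.

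Oxidative phosphorylation genes lay higher than in PA36 in (G4C2)36 (median log2 fold change 0.32) and lower in UPF1 RNAi (-0.18), and the test of the difference between these genotypes passed (median 0.48, camera adjusted p = 2.6e-14; adjusted p = 0.91 with an estimated correlation). Muscle markers did the same, at 0.71 and -0.27, with a difference of 0.95 (adjusted p = 1.5e-11; adjusted p = 0.77 with an estimated correlation). Gut digestive enzymes, with 3 members tested, lay lower in PR36 (3 of 3 below 0, median -0.64) and higher in (G4C2)36 (2 above and 1 below 0, median 1.47). The difference was -2.37, with 2 members lower and 1 higher in PR36 (camera adjusted p = 0.00028; adjusted p = 0.58 with an estimated correlation). Each was singled out because it was called in opposite directions and the difference itself was called. Each opposition rests on single libraries, however. Without PA36 replicate 1, the UPF1 RNAi calls were lost for oxidative phosphorylation (-0.10, adjusted p = 0.17) and muscle (-0.03, adjusted p = 0.77). The (G4C2)36 oxidative phosphorylation call was lost without PA36 replicate 2 (0.24, adjusted p = 0.42). The gut call was lost in PR36 without PR36 replicate 1 (-0.24, adjusted p = 0.49) and in (G4C2)36 without (G4C2)36 replicate 2 (0.71, adjusted p = 0.3).

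Of the 82 genes called in any comparison with PA36, 40 were at or near 0 in every library of a genotype. Values that fail at random in single libraries are argued against for the genotypes with 2 libraries, whose pairs stood apart from the 5 others by over 2 on the log2 scale in a mean of 10 genes, against a median of 2 and at most 8 for 18 pairs of different genotypes, although the PR36 pair alone, at 5, lay below that. For UPF1 RNAi such failures may account for the pattern, since this library stood apart in 36 genes and the 6 others in 18 to 37. Other accounts stay open: reads assigned differently between overlapping genes (odds ratio of overlap 0.71, two-sided Fisher's exact p = 0.34, and an overlapping partner moving the opposite way for 33.3%, or 3 of 9), transcripts missing from the table (odds ratio of a complete listing 1.37, exact p = 0.67), and a linked chromosome stretch that differs between fly lines (10% within 200 kb of another, random sets 0 to 30 with a median of 15). These cannot be told apart from an effect of the transgenes, because the genes are too few and the genetic backgrounds are not given in the sources used here.

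Heat shock genes were high in PA36 replicate 1 and PR36 replicate 1, and not in the second library of either genotype. A swap of these labels is argued against by 12 genes that set both PA36 libraries apart from the 5 others, against at most 2 for a crossed pair, while the share of 50 genes that kept their sign between replicates, 58.0%, met the bound set for a swap but separated little, being 70.0% and 62.0% for other genotypes. Exchanging the labels of these libraries would leave both first replicates high. The test therefore bears on the labels and not on the source of the heat shock values. One condition shared by all first replicates is argued against by the (G4C2)36 libraries, where the list's median differed by 0.13 and not by 3.11 or 3.7. A wide difference in RNA quality or composition cannot be told apart from a heat shock response of those flies, since the list made up 34.3% (12 of 35, 95% Wilson interval 20.8 to 50.8) of genes that differed by over 2 the same way in both pairs, and 23 other genes went the same way while 20 went opposite ways. No label gives a treatment that could set those libraries apart, so no biological explanation was tested.

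The 9 genes that differ from PA36 in all 3 comparisons, v, Fdh, Cnx99A, S6kII, CG32091, Cp1, CG12395, Uhg1 and hpRNA:CR33940, all moved the same way in each. CG12395, Uhg1 and hpRNA:CR33940 were not called in any of these comparisons with a pseudocount of 0.1. Chance values of shared PA36 libraries are argued against for pairs of comparisons: with a PA36 library of its own for each, 8 to 15 genes were still called the same way in both, from 66.7 to 93.8% as many as with both libraries shared, where independent lists would share at most 0.45. This speaks only to values of single libraries. No label says that the 2 PA36 libraries came from separate cultures, so a chance state common to both is not argued against. Of the 9, 0 were called between any pair of the other genotypes, which both a property of the PA36 line, such as a marker allele of v, and a shared response of the other genotypes would give. With PA36 as the only control, these cannot be told apart.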

How the results depend on the processing

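The fit without PA36 replicate 1 and PR36 replicate 1 and the genes with every transcript listed were chosen after seeing the data, and the other alternatives before. The cause was not tested for any change below, apart from what a setting's construction shows. Called genes, in the order PR36, (G4C2)36 and UPF1 RNAi against PA36, then PR36 against (G4C2)36, PR36 against UPF1 RNAi and (G4C2)36 against UPF1 RNAi, numbered 18, 36, 58, 22, 40 and 54. Counts within 1.5 times of these are left out. Without a filter on low values they were 7 for the first, 65 for the fifth and 88 for the last, and most calls involving UPF1 RNAi then were higher in it (58 of 79, 48 of 65 and 53 of 88), and with a filter at a mean of 5 TPM 11 for the first. Robust moderation gave 28, 61, 39, 72 and 106 for all but UPF1 RNAi against PA36. Fits on the groups compared alone gave 69 for (G4C2)36 and 0 for UPF1 RNAi against PA36, and 37, 1 and 343 between genotypes. Without both libraries with high heat shock genes, where the (G4C2)36 pair alone gives the spread, the counts were 198, 288, 243, 245, 261 and 338. Leaving out 1 replicate at a time gave 40 to 57, 22 to 86, 73 to 93, 24 to 68, 54 to 74 and 36 to 38, where a genotype left with 1 library was assumed to vary like the others. Leaving out the UPF1 RNAi library was not run, as it is the only one. Rescaling to coding genes moved (G4C2)36 against UPF1 RNAi from 44 higher and 10 lower to 40 and 16.

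Replicate numbers did not pair the samples: deviations of same-numbered libraries correlated at 0.097, -0.074 and -0.077. With the replicate number as a block, the counts were 33 for PR36, 57 for (G4C2)36, 66 for UPF1 RNAi, and 44, 56 and 87 between genotypes. List calls were 57, of which 44 were among the 52 of the fit without it, and 2 of 71 named calls against PA36 were not made (Cyp4d20 and hpRNA:CR33940 in UPF1 RNAi). Against PA36 the block added list calls for heat shock (camera adjusted p = 0.019) and fat body genes (0.0053) in (G4C2)36. In UPF1 RNAi it added SR splicing factors, immune effectors, gut enzymes and cuticle genes. In PR36 it ended the antioxidant (0.063), fat body (0.061) and chemosensory (0.096) calls.

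Of 71 named calls against PA36, none turned direction. A pseudocount of 0.1 ended 21 and the median-of-ratios rescaling 8 (in PR36 Eh at adjusted p = 0.071, Su(fu) at 0.085, sgll and hpRNA:CR33940 at 0.062; in (G4C2)36 Amy-d at 0.17 and lectin-46Cb at 0.098; in UPF1 RNAi Cyp4e3 at 0.098 and ND-39 at 0.14). Leaving out PA36 replicate 1 ended 9, PA36 replicate 2 7, either PR36 library 0 of 18, and (G4C2)36 replicate 1 or 2 13 or 11 of 25.

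All 52 list calls were lost with an estimated correlation, which left 0. Median-of-ratios rescaling kept 43 and added 5: oxidative phosphorylation lower in PR36 than in PA36 (adjusted p = 0.0022), proteasome genes lower in UPF1 RNAi than in PA36 (0.006), nucleocytoplasmic transport higher (0.03) and glial markers lower (0.025) in PR36 than in (G4C2)36, and the unfolded protein list lower in (G4C2)36 than in UPF1 RNAi (0.026). Like every list call, these are not made with an estimated correlation. A pseudocount of 0.1 kept 50 and added that glial call (0.043). Some raw list medians changed sign. In PR36, antioxidants had 0 as reported, -0.12 with median of ratios, and -0.08 to 0.09 over single replicates left out. Ribosomal proteins had -0.02, then 0.04 without both heat shock libraries and -0.09 to 0.06 over single replicates. Fat body genes had 0.05, then -0.08 with median of ratios and -0.14 to 0.10. Chemosensory genes had -0.03, then 0.12 without both libraries and -0.20 to 0.19. The median over all genes moved too, from 0.126 to 0.007 with median of ratios and to between 0.04 and 0.205 over single replicates. Relative to it, antioxidants and fat body genes lay at -0.12 and -0.08 as reported, so the rescaling turned neither. In (G4C2)36 the nucleolus list (-0.22) ranged from -0.46 to 0.07, while the median over all genes ranged from -0.027 to 0.312. The 0.07 and the 0.312 belong to the same fit, without (G4C2)36 replicate 2. In UPF1 RNAi heat shock genes (-1.23) ranged from -3.03 to 0.33, with 0.33 without both libraries. Over single replicates left out, other medians ranged in PR36 from -1.05 to -0.24 for gut enzymes and from 0.16 to 0.97 for marker loci. In (G4C2)36 they ranged from 0.31 to 0.75 for NMD targets, 0.23 to 0.76 for cuticle genes and 0.71 to 2.22 for gut enzymes. In UPF1 RNAi the ranges were -0.41 to -0.23 for fat body, -0.40 to -0.03 for muscle, -0.26 to -0.10 for oxidative phosphorylation, -0.34 to -0.01 for nucleolus and 0.25 to 0.62 for synaptic genes. Without both, 15 of 26 list calls against PA36 were lost or turned.

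With 1 PA36 library for each comparison, the correlation of fold changes was 0.02 and 0.06 for PR36 with (G4C2)36, 0.07 and -0.06 for PR36 with UPF1 RNAi, and 0.12 and -0.03 for (G4C2)36 with UPF1 RNAi. The 12 genes shared by PR36 and UPF1 RNAi became 7 with a filter at 5 TPM. The unknown depth leaves open how much of any 0 is sampling.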

Other observations

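Of the tests in this part, the comparison of each excess with that between replicate libraries was chosen only after the percentiles had been seen. Several gene groups of interest for C9orf72 repeats did not separate from other genes against PA36. Nucleocytoplasmic transport genes had medians of 0.20, 0.11 and 0.07 in PR36, (G4C2)36 and UPF1 RNAi (camera adjusted p = 0.18, 0.76 and 0.77), and SR splicing factors of 0.15, 0.10 and 0.26 (adjusted p = 0.8, 0.82 and 0.14). Antimicrobial peptides and immune effectors had medians of 0.18, 0.07 and -0.12 (adjusted p = 0.91, 0.82 and 0.1), and Turandot and JAK-STAT targets of 0.25, 0.11 and 0.10 (adjusted p = 0.8, 0.82 and 0.81). With the replicate number as a block, SR splicing factors and immune effectors were called in UPF1 RNAi, although these numbers did not pair the samples. Apoptosis and DNA damage genes (0.15, -0.03 and 0.03), phototransduction genes (0.15, 0.21 and 0.15), glial markers (0.04, 0.28 and 0.12) and autophagy genes (0.13, 0.15 and 0.04) were not called either, although Cp1 of the last list fell in all 3 comparisons. Cytochrome P450s went both ways in UPF1 RNAi, where Cyp4e3 rose, Cyp4d20 fell and Cyp12a5 was listed at 0 (list median 0.03, camera adjusted p = 0.61).

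Proteasome genes were not called against PA36, except as lower in UPF1 RNAi with median-of-ratios rescaling (camera adjusted p = 0.006), but were higher in (G4C2)36 than in UPF1 RNAi (29 of 32, median 0.24, camera adjusted p = 0.007; adjusted p = 0.94 with an estimated correlation) and lower in PR36 than in (G4C2)36 (28 of 32, median -0.12, adjusted p = 0.046; adjusted p = 0.98 with an estimated correlation). Hemocyte markers were higher in PR36 than in UPF1 RNAi in 9 of 9 genes (median 0.49, adjusted p = 0.0054; adjusted p = 0.90 with an estimated correlation). The 10 circadian clock genes were higher in PR36 than in (G4C2)36 in 9 cases (median 0.39, adjusted p = 0.00053; adjusted p = 0.58 with an estimated correlation). Within the fat body list, the (G4C2)36 libraries differed from each other: Yp3 stood at 24440 and 45250 TPM and Fbp1 at 4.69 and 13.4 TPM, against 0.137 and 0.0226 TPM for Fbp1 in PA36, but neither gene passed against PA36 (adjusted p = 0.58 and adjusted p = 0.1).

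A hypothesis was that transcripts with features that expose them to NMD are higher where NMD is impaired. Among 15275 listed transcripts, 587 had a stop codon at least 50 nt before the last exon junction and 3059 had a 3' UTR of at least 947 nt. The former are called early-stop transcripts below. They were picked by their annotated stop alone, and whether NMD acts on them in these heads was not tested. In UPF1 RNAi, early-stop transcripts had a median log2 fold change of 0.29 against 0.11 (0.06 to 0.15) for random sets matched on mean TPM, at percentile 100 of 10000, and 66.8% were higher. That excess of 0.19 was larger than the highest between replicate libraries, 0.07. Weaker decay of such transcripts in this single library could give it, but decay was not measured. Long 3' UTRs lay at percentile 100 too, but their excess of 0.17 was close to the 0.13 seen between replicates, so the test leaves them open. In PR36 both sets lay at percentile 100 and passed the bound set beforehand. Early-stop transcripts had a median of 0.2 against 0.09 to 0.15 for random sets, and their excess of 0.08 was slightly above the highest between replicates (0.07). The single PR36 libraries gave 0.18 and 0.22, for which no random range of their own is given. The excess of 0.04 for long 3' UTRs was below that between replicates (0.13). In (G4C2)36 the percentiles were 95.8 and 13.1, and the latter set's median of 0.12 lay inside the random range of 0.11 to 0.14, so its low percentile excludes nothing. With 3 replicate pairs to set the scale, weaker decay in PR36 and in (G4C2)36 stays open.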
